A study of Mus musculus with 40 samples.

How the data were processed

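The data were translating ribosome affinity purification sequencing of mouse brain (TRAP-seq). In this assay 1 cell type makes an EGFP-tagged ribosomal protein, and its ribosomes and their RNA are pulled down with antibodies against EGFP. Here the tag was Rpl10a under the Aldh1l1 promoter, which is active in astrocytes, so the counts describe ribosome-bound RNA of astrocytes together with whatever RNA of other cells was carried along. Per the labels' protocols, mice met an aggressive CD1 mouse for 10 minutes a day over 10 days (chronic social defeat) and were then screened for social interaction. Mice with an interaction index below 1 formed the stressed group, which is also called susceptible, mice with an index above 1 formed the resilient group, and control mice were not defeated. Tissue was taken 2 days later, and each library came from a pool of at least 2 mice, with 4 to 6 mice per pool for the nucleus accumbens. Inputs of unpurified tissue were not analysed here, so enrichment over whole tissue was not measured.

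The deposited values were whole-number read counts per gene symbol, 1 column per library, made with STAR 2.0.0e and HTSeq against mm10, per the submitters' processing notes. The HTSeq version, gene annotation, counting mode and strand setting are not given in the sources. Overlapping and antisense genes such as Six3 and Six3os1 can therefore have shared reads. Near-identical genes can lose or exchange reads too, among them the haemoglobin genes (Hbb-b2, Hbb-bs), the class I histocompatibility genes (H2-K1, H2-D1, H2-T23), the pseudogene Bambi-ps1 and ribosomal protein genes such as Rps27. Values of these genes are uncertain in that respect. The 5 closing lines of HTSeq, which count reads outside genes, were read apart from the genes.

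There were 40 libraries in 12 groups, 4 regions by 3 conditions. Total counts in genes ran from 21.3 to 33.0 M per library with a median of 25.6 M, and 17485 to 19214 genes had at least 1 count. The 10 most abundant genes took 6.44% to 11.5% of the counts. Reads outside genes were 17.0% to 20.1% of all reads counted, and reads with more than 1 alignment 10.4% to 13.2%. Libraries of a group were compared before they were averaged. In all 52 pairs their counts differed by more than sampling noise (chi-square per degree of freedom 8.25 to 293, over genes with a summed count of at least 20), so none was treated as a repeat of another. The labels say that libraries are pools of separate mice, but not which mice gave several regions, so p-values measure the spread between pools.

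Genes with too few counts were removed with the filterByExpr function of edgeR, and library sizes were scaled by TMM factors. The test was the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with 1 fit per region in which the 3 conditions shared their spread. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. All adjusted p-values of single genes in the text come from this test unless another tool is named, and all tests were two-sided. In control libraries a joint test with 3 degrees of freedom compared the 4 regions, and each region was then set against the mean of the other 3. The same kind of test over all 40 libraries asked whether the effect of stress differed between regions. Standard errors of log2 fold changes (SE) came from the fitted model, and counts per M counts (CPM) are given as mean ± SD over the libraries of a group.

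The 36 gene lists covered the studied cell type (astrocyte core), 14 other cell types (general, excitatory, inhibitory and striatal projection neurons, oligodendrocytes and their precursors, microglia and macrophages, endothelial and mural cells, ependymal cells, choroid plexus, meningeal fibroblasts, red blood cells, neural progenitors), 3 states of reactive astrocytes and 18 pathways or gene families. Of these, 35 were tested; the mitochondrial-encoded list had fewer than 4 measured members and was not tested. Lists were tested with camera of limma 3.58.1 at its preset correlation between genes of 0.01, adjusted over the 35 lists of a comparison. The test was repeated with the correlation estimated from the data and with fry. For 15 cell-type lists a marker level was computed per library, the mean log2 CPM of the members with a prior count of 2, and compared with exact permutation tests adjusted over the 45 comparisons of a region. Some markers are also made by astrocytes at a low level, and lists share a few genes.

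The groups, tests, gene lists, alternatives and rules for naming genes were chosen before the data were examined. The rule took from each stressed comparison up to 8 genes per direction with the largest change among called genes with a mean log2 CPM of at least 1 (5 for resilient against control), or, where fewer than 3 genes were called, the 2 per direction with the smallest p. It added up to 8 genes called in both stressed comparisons of a region with the smallest larger p, up to 4 members of each list, 5 reference genes (Aldh1l1, Gfap, Aqp4, Slc1a2, Gja1), up to 8 higher and 4 lower genes per region with a mean log2 CPM of at least 3, and up to 6 genes for each interaction. Genes with only a systematic or clone name were passed over. After values were seen this was extended to further accession-like symbols, and the numbers printed were reduced, in the order of the rule, to 2 members per list, 4 higher and 2 lower genes per region and 2 genes per interaction. Some list members that this rule selects are not reported here. The reference genes are printed for the stressed comparisons of the prefrontal cortex. Rn45s was singled out after its values were seen.

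Alternatives chosen before the data were examined were DESeq2 1.42.0, limma voom with quality weights, RLE factors, no filter on low counts, all 40 libraries in 1 fit, the replicate number as a block, a term for the form of the deposited names, the mean level of neuron, oligodendrocyte, microglia and endothelial markers as a covariate, and leaving out each library in turn. The names came in a long form (16 libraries) or in a short form with single letters (24 libraries), which may stand for a batch; all libraries of the caudate putamen had the short form. Alternatives added after the data were seen were removal of each library's trend on transcript length and GC content, comparisons within 1 naming form, and fits without prefrontal stressed replicates 4 and 5, without prefrontal stressed replicates 1 to 3, or without hippocampal stressed replicates 2 and 3. Lengths and GC content were those of GENCODE vM21 transcripts and were found for 94% of the genes called and 91.3% of the genes tested in the prefrontal stressed against control comparison. Positions of genes are 1-based on mm10 (GRCm38) from the same annotation.

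The labels give the same replicate numbers to different groups. In 1 comparison, nucleus accumbens resilient against control, all 3 pairs of libraries with the same number correlated above 0.1 (0.402 to 0.773, across genes after removal of group means), and there a paired fit with the replicate number as a block also called 0 genes. In the other comparisons the correlations ran from −0.508 to 0.835, and the numbers were not taken to pair libraries.

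Simulations had 200 genes changed by known folds. In counts simulated for prefrontal stressed against control (15324 genes), edgeR recovered 11.9%, 64.2% and 98.5% of genes changed 1.5-, 2- and 4-fold. Of its calls 3.33% were false. The matching shares were 0%, 23.9% and 83.3% for hippocampal stressed against control (15531 genes), 4.48%, 47.8% and 92.4% for the nucleus accumbens (15136 genes) and 1.49%, 47.8% and 93.9% for the caudate putamen (14755 genes). For the interaction of region and stress against control (16387 genes) they were 1.49%, 23.9% and 92.4%, and for region differences (15731 genes) 0%, 25.4% and 90.9%. DESeq2 made 23.4% false calls in simulated prefrontal stressed against control. Camera called a simulated list of 20 shifted genes (either correlation) and 0 of 35 random lists. Random lists do not test the preset on genes that move together. With an estimated correlation even 13 of 13 called striatal genes were missed (caudate putamen), so a lost call decides little. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.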

Results

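Ribosome-bound RNA of astrocytes was sequenced from 4 brain regions of mice after 10 days of social defeat. Each region had undefeated control mice, resilient mice that still sought social contact, and stressed (susceptible) mice that avoided it. The prefrontal cortex had 3 control, 4 resilient and 5 stressed libraries, the hippocampus 3, 3 and 5, the nucleus accumbens 3, 3 and 4, and the caudate putamen 2, 2 and 3. Total counts in genes were 21.7 to 28.1 M per library in the prefrontal cortex, 21.8 to 30.3 M in the hippocampus, 23.3 to 33.0 M in the nucleus accumbens and 21.3 to 26.2 M in the caudate putamen. The most abundant gene of each library was Aldoc or Apoe, which astrocytes make in large amounts. The design asks which transcripts changed in stressed mice against both control and resilient mice, and in which region.

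Astrocyte fractions of the 4 regions differed in control mice. The caudate putamen fraction was rich in transcripts of striatal neurons. Drd2, a dopamine receptor, was higher than the mean of the other 3 regions by 4.80 ± 0.417 (log2 fold change ± SE, adjusted p = 0.000159), and Syndig1l by 4.73 ± 0.309 (adjusted p = 5.47e-05). Prss56 (5.73 ± 0.475, adjusted p = 0.000128) and Cd4 (5.26 ± 0.474, adjusted p = 0.000204) were higher there too. Aldh1a2 (−5.60 ± 0.833, adjusted p = 0.00399), an enzyme of retinoic acid synthesis, and Fmod (−5.12 ± 1.04, adjusted p = 0.0167) were lower. In the nucleus accumbens the genes with the largest differences were Six3os1 (4.62 ± 0.524, adjusted p = 0.00146), Crym (3.86 ± 0.396, adjusted p = 0.000867), Gpr6 (3.81 ± 0.5, adjusted p = 0.00396) and Six3 (3.79 ± 0.54, adjusted p = 0.00633). Six3os1 overlaps Six3 on the opposite strand, so their reads cannot be told apart without strand. The cortical transcription factor genes Emx1 (−2.87 ± 0.309, adjusted p = 0.000993) and Neurod6 (−2.35 ± 0.443, adjusted p = 0.0217) were lower in that region.

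The prefrontal fraction was higher in Cbln2, a synapse organizer (3.53 ± 0.238, adjusted p = 4.39e-05), Nrn1 (2.82 ± 0.231, adjusted p = 0.000131), Car10 (2.80 ± 0.208, adjusted p = 7.07e-05) and Igfbp6 (2.68 ± 0.312, adjusted p = 0.000766). It was lower in Six3os1 (−7.93 ± 0.932, adjusted p = 0.000796) and Ccdc153 (−7.86 ± 0.823, adjusted p = 0.000475). In the hippocampus, genes of the choroid plexus led. Ttr, which encodes transthyretin, stood at 4631 ± 3990 CPM (SD, n = 3) and differed by 10.02 ± 1.16 (adjusted p = 0.000635). Krt18 (8.31 ± 1.04, adjusted p = 0.00084) and Sostdc1 (7.99 ± 0.946, adjusted p = 0.00069) were higher as well, and Cd4 (−6.07 ± 0.77, adjusted p = 0.000914) and Prss56 (−5.61 ± 0.751, adjusted p = 0.0011) were lower. Kcne2 reached 31.7 ± 27.8 CPM in the hippocampus and was listed at 0 in all prefrontal controls, so no fold is given. All 11 choroid plexus genes measured were called higher in the hippocampus (11 adjusted over the list alone; median log2 fold change 7.99; camera adjusted p = 6.46e-07, adjusted p = 0.433 with an estimated correlation).

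Striatal projection neuron genes were called lower in the prefrontal cortex for 13 of 13 members (13 adjusted over the list alone; camera adjusted p = 1.99e-13, adjusted p = 0.403 with an estimated correlation). In the hippocampus 12 of 13 were called lower (camera adjusted p = 1.11e-15, adjusted p = 0.217 with an estimated correlation). In the nucleus accumbens 11 of 13 were called higher (13 adjusted over the list alone; camera adjusted p = 3.85e-21, adjusted p = 0.211 with an estimated correlation). In the caudate putamen 13 of 13 were called higher (camera adjusted p = 3.7e-19, adjusted p = 0.269 with an estimated correlation). Over all regions edgeR called 3024 of 16053 genes different. The comparisons of 1 region with the mean of the rest gave 963 genes higher and 1079 lower in the prefrontal cortex, 1409 and 752 in the hippocampus, 242 and 106 in the nucleus accumbens, and 547 and 353 in the caudate putamen. The joint count fell to 1806 without prefrontal control replicate 1, to 1784 without replicate 2 and to 1973 without replicate 3. It was 1811 with the replicate number as a block and 4913 with DESeq2.

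In the prefrontal cortex, stressed mice differed from control mice in many ribosome-bound transcripts. Lrp1, an endocytic receptor for apolipoprotein E and other ligands, rose from 27.8 ± 3.92 CPM (SD, n = 3) in control mice to 114 ± 11.8 CPM (n = 5) in stressed mice. Ppp1r9a, which encodes the actin-binding synaptic scaffold neurabin, rose by 3.58 ± 0.945 (log2 fold change ± SE, adjusted p = 0.0162). Genes for neurons, microglia, endoplasmic reticulum chaperones, calcium signalling and synapse-organizing secreted proteins rose as groups by camera at its preset correlation. These calls were lost for neurons and microglia (adjusted p = 0.358 with an estimated correlation) and for the other 3 groups (adjusted p = 0.32 with an estimated correlation). Aldh1l1, whose promoter drove the ribosome tag, and Gfap, the astrocyte intermediate filament, did not pass the test.

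Beside Ppp1r9a (mm10 chromosome 6, 4902917 to 5165661), the genes with the largest rises, clone names passed over, were Ctss (2.98 ± 0.573, adjusted p = 0.00364), a lysosomal protease of macrophages on chromosome 3 (95526786 to 95556403), and genes of molecular motors. Of these Myo5a (2.98 ± 0.864, adjusted p = 0.0238) and Myh10 (2.67 ± 0.732, adjusted p = 0.019) encode myosins and Dync1h1 (2.80 ± 0.776, adjusted p = 0.0198) the heavy chain of dynein. Next came Bsn (2.63 ± 0.497, adjusted p = 0.00333), a presynaptic scaffold, Mapk8ip2 (2.62 ± 0.865, adjusted p = 0.04), a kinase scaffold, and Ryr2 (2.60 ± 0.578, adjusted p = 0.00755), a calcium release channel. Stressed replicates 4 and 5 had a transcript length trend (correlations 0.424 and 0.372). The fold changes of Ppp1r9a, Myo5a, Dync1h1, Myh10 and Mapk8ip2 rested mainly on them. Without these replicates they were 1.19, 0.71, 0.98, 0.87 and 0.31, and Mapk8ip2 was no longer called (adjusted p = 0.28). Ppp1r9a stood at 230 ± 258 CPM in stressed mice, 19.2 ± 5.85 in control mice and 17.4 ± 3.41 in resilient mice. For Ctss the rise was 3.47 without stressed replicates 4 and 5 and 1.53 without replicates 1 to 3.

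Falls were smaller. Trp63, a transcription factor gene on chromosome 16 (25683763 to 25892102), fell from 8.75 ± 1.59 CPM in control mice to 3.81 ± 0.373 CPM in stressed mice (−1.20 ± 0.156, adjusted p = 0.000716). The other genes with the largest falls were Epb4.1l4a (−1.25 ± 0.307, adjusted p = 0.0114), Tgds (−1.18 ± 0.143, adjusted p = 0.000549), Epx (−1.14 ± 0.198, adjusted p = 0.00227) and Mettl11b (−1.10 ± 0.181, adjusted p = 0.00183). They were followed by Bambi-ps1 (−1.002 ± 0.153, adjusted p = 0.00124), a pseudogene whose reads can come from Bambi, Fbxl21 (−0.99 ± 0.163, adjusted p = 0.00184), an F-box gene, and Phyhd1 (−0.97 ± 0.205, adjusted p = 0.00575). Among the reference genes, the glutamate transporter gene Slc1a2 (1.54 ± 0.435, adjusted p = 0.0214), the connexin gene Gja1 (0.99 ± 0.27, adjusted p = 0.0189) and the water channel gene Aqp4 (0.90 ± 0.305, adjusted p = 0.0439) rose. Aldh1l1 (0.03 ± 0.158, adjusted p = 0.897) and Gfap (−0.15 ± 0.111, adjusted p = 0.323) did not pass. Without stressed replicates 1 to 3, Slc1a2, Gja1 and Aqp4 stood at 0.26, 0.44 and 0.03 and were not called. The sign of Aldh1l1 was not stable, with −0.30 within the short naming form and 0.28 within the long one.

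With edgeR, 2536 genes were called higher and 1817 lower, 4353 of 15491 tested, and 1336 of them changed more than 2-fold. The median called change was 1.02 for higher and −0.47 for lower genes. Leaving out control replicate 1 left 1533 genes and leaving out control replicate 2 left 2178, 0 genes were called with the marker level as a covariate, and a fit with the replicate number as a block called 2875. Within the long naming form 8394 genes were called (2 control and 2 stressed libraries), and within the short form 3764 (1 control and 3 stressed libraries, the lone control being assumed to vary like the other groups). The stressed libraries were of 2 kinds: without replicates 4 and 5 the count was 5818, and without replicates 1 to 3 it was 7600.

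**Figure D1:**
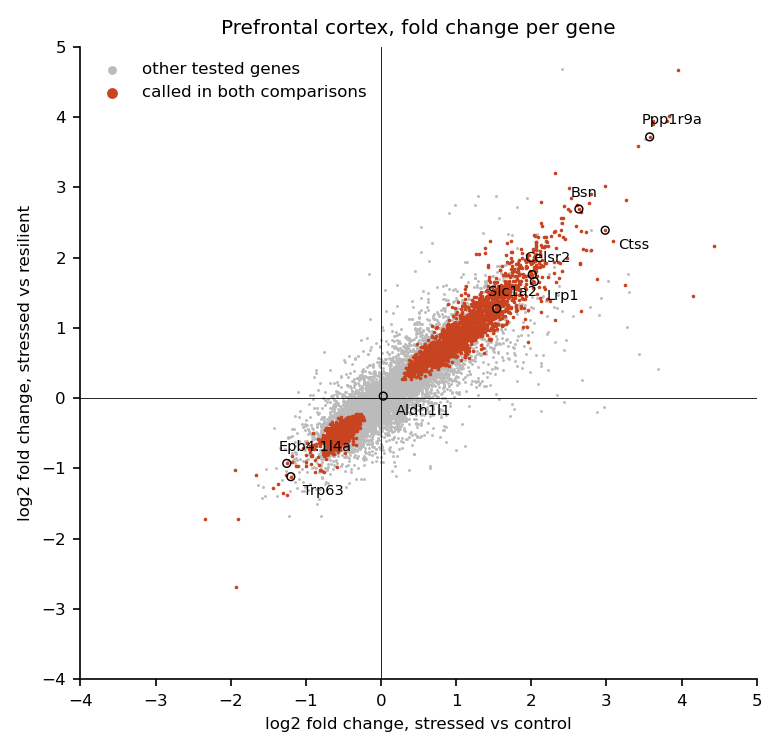
Log2 fold changes of prefrontal genes, stressed against control on 1 axis and stressed against resilient on the other, with each tested gene as a point, genes called in both comparisons in red and some named genes circled. Across genes, which are not independent replicates, the 2 sets of fold changes correlated with r = 0.9, and both share the 5 stressed libraries.

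Several cell-type groups rose in stressed against control mice. Of 16 general neuron genes, 11 rose and 0 fell (15 and 0 adjusted over the list alone; median log2 fold change 0.97; camera adjusted p = 4.66e-05, adjusted p = 0.358 with an estimated correlation). Syt1, a synaptic vesicle calcium sensor, went from 151 ± 12.6 to 266 ± 21 CPM (0.81, adjusted p = 0.000671), and Stmn3 stood at 0.85 (adjusted p = 0.00717). Of 12 excitatory neuron genes 8 rose (10 adjusted over the list alone; camera adjusted p = 0.000351, adjusted p = 0.358 with an estimated correlation), such as Grin2b (1.27, adjusted p = 0.000537) and Slc17a7 (1.54, adjusted p = 0.00407). Of 12 inhibitory neuron genes 7 rose (10 adjusted over the list alone; camera adjusted p = 0.00104, adjusted p = 0.132 with an estimated correlation), such as Reln (2.19, adjusted p = 0.00324) and Sst (1.57, adjusted p = 0.00572). Of 13 striatal projection neuron genes 6 rose (7 adjusted over the list alone; camera adjusted p = 0.00456, adjusted p = 0.358 with an estimated correlation). Among them were the neuropeptide genes Penk (1.43, adjusted p = 0.000991) and Tac1 (1.39, adjusted p = 0.00372). General neuron genes numbered 10 higher without stressed replicates 4 and 5 and 14 higher without replicates 1 to 3.

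Of 15 microglia and macrophage genes 10 rose and 0 fell (10 adjusted over the list alone; median log2 fold change 1.42; camera adjusted p = 0.000119, adjusted p = 0.358 with an estimated correlation). Examples are Csf1r, a growth factor receptor (2.02, adjusted p = 0.0028), and Tmem119 (1.42, adjusted p = 0.00343). The count was 12 without stressed replicates 4 and 5 and 3 without replicates 1 to 3. Of 11 endothelial genes 5 rose (6 adjusted over the list alone; camera adjusted p = 0.00374, adjusted p = 0.454 with an estimated correlation), with Egfl7 at 1.12 (adjusted p = 0.00379) and Itm2a at 1.32 (adjusted p = 0.00426). Here the count was 4 without replicates 4 and 5 and 11 without replicates 1 to 3. Of 11 meningeal fibroblast genes 5 rose (8 adjusted over the list alone; camera adjusted p = 0.00825, adjusted p = 0.586 with an estimated correlation). They include Slc22a6 (1.32, adjusted p = 0.0139) and Col1a1 (1.15, adjusted p = 0.0169), and 0 were called higher without replicates 1 to 3. Of 9 mural cell genes 4 rose (4 adjusted over the list alone; camera adjusted p = 0.035, adjusted p = 0.358 with an estimated correlation), Vtn by 1.86 (adjusted p = 0.0053). Of 14 oligodendrocyte genes 5 rose (6 adjusted over the list alone; camera adjusted p = 0.0237, adjusted p = 0.511 with an estimated correlation), such as Trf (1.53, adjusted p = 0.00108) and Enpp2 (1.36, adjusted p = 0.00483).

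The remaining cell-type lists were not called. Of 11 oligodendrocyte precursor genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.174), with Pdgfra at 1.71 (adjusted p = 0.00275) and Cspg4 at 1.42 (adjusted p = 0.0102). Of 6 ependymal genes Dnah5 (2.01, adjusted p = 0.049) rose (0 adjusted over the list alone; camera adjusted p = 0.723). This list had a median of −0.20 and a mean of 0.24 while its test pointed down; Foxj1 stood at −0.38 (adjusted p = 0.201). No gene passed among 4 choroid plexus genes (0 adjusted over the list alone; camera adjusted p = 0.379; Ttr 2.80, adjusted p = 0.0647; Aqp1 1.64, adjusted p = 0.142). The same held for 4 red blood cell genes (0 adjusted over the list alone; camera adjusted p = 0.35; Hbb-b2 0.84, adjusted p = 0.197; Hbb-bs 0.84, adjusted p = 0.218). It also held for 8 neural progenitor genes (0 adjusted over the list alone; camera adjusted p = 0.799; Eomes 3.68, adjusted p = 0.0646).

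Astrocyte genes rose more often than they fell. Of 24 core astrocyte genes 9 rose and 2 fell (10 and 2 adjusted over the list alone; median log2 fold change 0.46; camera adjusted p = 0.362). Those that rose include the bicarbonate transporter gene Slc4a4 (0.99, adjusted p = 0.0132). The counts were 14 higher and 2 lower without stressed replicates 4 and 5, and 1 higher and 7 lower without replicates 1 to 3. Of 19 genes of glutamate and GABA handling 12 rose (13 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00174, adjusted p = 0.32 with an estimated correlation). They include Gabbr2, a GABA receptor subunit (1.12, adjusted p = 0.00118), and the cystine transporter gene Slc7a11 (0.85, adjusted p = 0.00338). Of 18 genes of potassium, water and gap junction handling 10 rose (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00987, adjusted p = 0.586 with an estimated correlation). Among them were the chloride channel gene Clcn2 (1.03, adjusted p = 0.000952) and the cotransporter gene Slc12a2 (1.18, adjusted p = 0.00102). Of 25 neuromodulator receptor genes 7 rose (7 adjusted over the list alone; camera adjusted p = 0.0064, adjusted p = 0.32 with an estimated correlation), with Cnr1 at 0.99 (adjusted p = 0.0103) and Adrb1 at 0.68 (adjusted p = 0.0169). Neuron, microglia and endothelial genes rose too, but the last mainly without replicates 1 to 3.

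Of 22 synapse-organizing secreted and matrix genes 16 rose and 1 fell (20 and 1 adjusted over the list alone; median log2 fold change 1.21; camera adjusted p = 1.77e-06, adjusted p = 0.32 with an estimated correlation). An example is the thrombospondin gene Thbs2 (1.80, adjusted p = 0.00103). Of 25 chaperone and unfolded protein response genes 15 rose and 0 fell (18 and 0 adjusted over the list alone; median log2 fold change 1.04; camera adjusted p = 4.1e-05, adjusted p = 0.32 with an estimated correlation). Higher genes include Hspa5, the main chaperone of the endoplasmic reticulum (1.42, adjusted p = 0.000952), and the calnexin gene Canx (1.67, adjusted p = 0.00176). Of 26 genes of calcium and cyclic AMP signalling 14 rose (15 adjusted over the list alone; camera adjusted p = 4.1e-05, adjusted p = 0.32 with an estimated correlation). Calcium pump genes led, Atp2b4 by 1.72 (adjusted p = 0.000386) and Atp2b1 by 1.98 (adjusted p = 0.000952). Of 18 lipid transport genes 10 rose and 2 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.00562, adjusted p = 0.396 with an estimated correlation), with Lrp1 at 2.04 (adjusted p = 0.000132) and Vldlr at 1.28 (adjusted p = 0.000786). Without stressed replicates 4 and 5, and without replicates 1 to 3, the higher genes were 19 and 12 of the synapse-organizing list, 18 and 13 of the chaperones, 16 and 18 of calcium signalling, and 13 and 7 of lipid transport. In the last fit 6 lipid transport genes were lower. The same stressed libraries had higher neuron, microglia and endothelial markers, by 0.97, 1.20 and 1.29 in mean log2 CPM against control.

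Ribosomal protein genes were slightly lower. Of 81, 0 rose and 6 fell (0 and 0 adjusted over the list alone; median log2 fold change −0.18; camera adjusted p = 0.00017, adjusted p = 0.706 with an estimated correlation). Rps27 stood at −0.50 (adjusted p = 0.00857) and Rpl7l1 at −0.46 (adjusted p = 0.0147). Nuclear genes of oxidative phosphorylation had 4 lower of 34 (0 adjusted over the list alone; median −0.23; camera adjusted p = 0.00873, adjusted p = 0.632 with an estimated correlation). Lower ones include Cyc1 (−0.38, adjusted p = 0.0151) and Ndufb10 (−0.41, adjusted p = 0.031). The 2 kinds of stressed libraries differed here. Replicates 4 and 5, with the length trend, had 75 ribosomal protein genes lower (median −0.58). Replicates 1 to 3 had 8 higher and 6 lower (median 0.02). Inflammatory reactive astrocyte genes rose for 3 of 11 (3 adjusted over the list alone; camera adjusted p = 0.0273, adjusted p = 0.437 with an estimated correlation). These include the histocompatibility genes H2-T23 (1.36, adjusted p = 0.000817) and H2-D1 (1.45, adjusted p = 0.00867), which have near-identical relatives. Microglia markers were higher in the same libraries.

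The lists below the threshold of camera held single changed genes. Among 12 general reactive genes 3 rose (3 adjusted over the list alone; camera adjusted p = 0.225; Cp 1.21, adjusted p = 0.0253; Serpina3n 1.04, adjusted p = 0.0255). Among 7 ischaemic reactive genes 1 did, Ptgs2 (1.77, adjusted p = 0.034; 0 adjusted over the list alone; camera adjusted p = 0.962). The list had a median of −0.09, a mean of 0.19 and a test that pointed up, with Tm4sf1 at 0.64 (adjusted p = 0.155). Of 20 glucocorticoid response genes 1 rose, Zbtb16 (1.14, adjusted p = 0.00245), and 5 fell, such as Sult1a1 (−0.76, adjusted p = 0.0139), with 1 and 6 adjusted over the list alone (camera adjusted p = 0.228). Of 26 immediate early genes Cyr61 rose (0.82, adjusted p = 0.026) and Zfp36 fell (−0.56, adjusted p = 0.0333; 0 and 0 adjusted over the list alone; camera adjusted p = 0.807). Of 18 clock genes Ciart rose (0.80, adjusted p = 0.00688) and 3 fell, among them Rorb (−0.37, adjusted p = 0.00526; 1 and 3 adjusted over the list alone; camera adjusted p = 0.725). Here the median was 0.00, the mean 0.06, and the test pointed down.

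Cholesterol synthesis genes rose for 9 of 24 and fell for 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.137). Cyp51 rose by 1.33 (adjusted p = 0.00289). Glycolysis, glycogen and lactate genes rose for 4 of 26 and fell for 2 (2 and 2 adjusted over the list alone; camera adjusted p = 0.587). Those that fell included Ppp1r3c (−0.60, adjusted p = 0.00487) and Pygm (−0.52, adjusted p = 0.0162), a scaffold and an enzyme of glycogen metabolism. Trophic factor genes rose for 3 of 21 (2 adjusted over the list alone; camera adjusted p = 0.588), with Bdnf at 1.00 (adjusted p = 0.00103) and Igf1 at 1.249 (adjusted p = 0.00693). Interferon response genes rose for 2 of 24 (0 adjusted over the list alone; camera adjusted p = 0.543; H2-K1 1.33, adjusted p = 0.0202; B2m 1.17, adjusted p = 0.0453). NF-kB and cytokine genes rose for 3 of 18 (1 adjusted over the list alone; camera adjusted p = 0.409; Cxcl12 0.89, adjusted p = 0.0135; Tnfrsf12a 1.01, adjusted p = 0.03). Camera at its preset correlation called 19 of 35 lists in this comparison, and 0 with an estimated correlation.

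**Figure D2:**
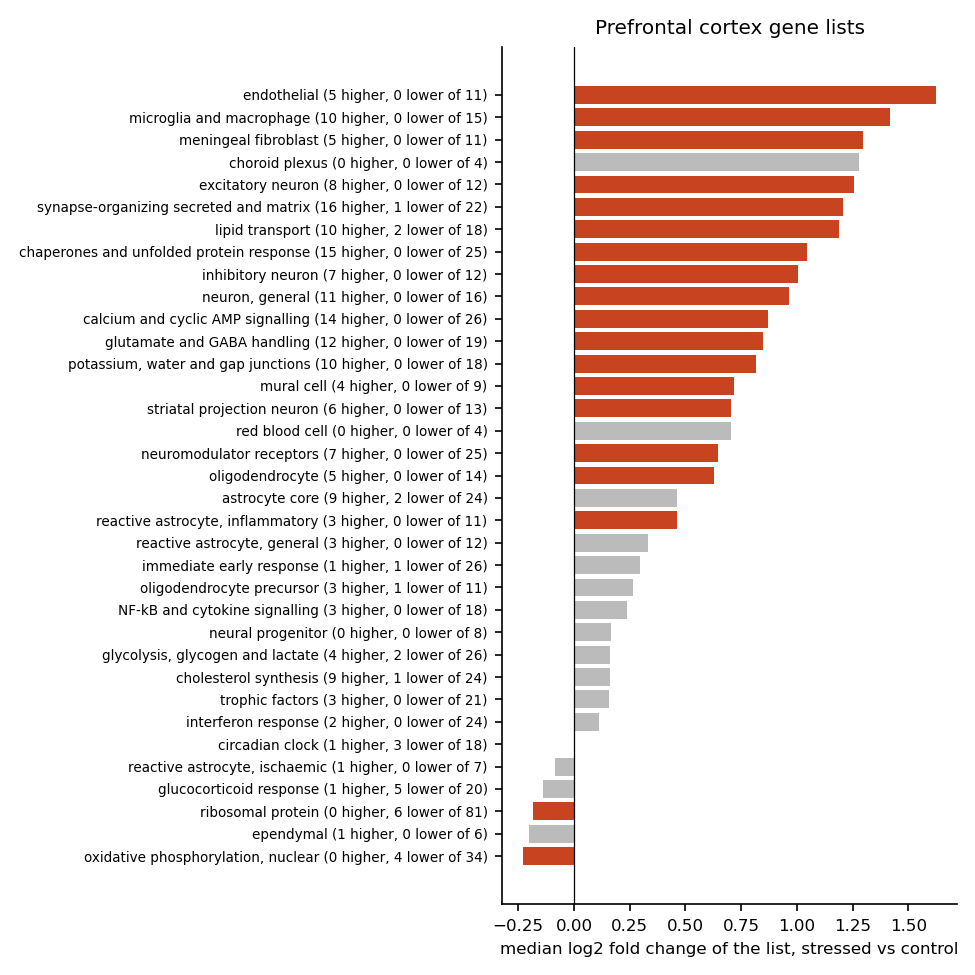
Median log2 fold change of each gene list in prefrontal stressed against control libraries, 1 bar per list starting at 0, with the numbers of members called higher and lower beside the list's name. Red bars are lists with a camera adjusted p under 0.05 at the preset correlation, grey bars the others. The synapse-organizing list (16 higher, 1 lower) and the chaperones (15 higher, 0 lower) lie to the right of 0, and ribosomal proteins (0 higher, 6 lower) to the left.

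Stressed mice also differed from resilient mice in the prefrontal cortex. Ppp1r9a rose by 3.72 ± 0.841 (adjusted p = 0.00875), Myo5a by 3.02 ± 0.767 (adjusted p = 0.0147) and Dync1h1 by 2.91 ± 0.693 (adjusted p = 0.011). The spectrin genes rose too, Sptan1 by 2.85 ± 0.637 (adjusted p = 0.00837) and Sptbn1 by 2.70 ± 0.6 (adjusted p = 0.00811). Mapk8ip2 rose by 2.75 ± 0.775 (adjusted p = 0.0227), the collagen gene Col6a1 by 2.74 ± 0.459 (adjusted p = 0.00217) and Bsn by 2.69 ± 0.443 (adjusted p = 0.00203). Trp63 fell by 1.12 ± 0.145 (adjusted p = 0.000802), and so did Zfp808 (−1.03 ± 0.222, adjusted p = 0.00688), Klhl15 (−1.02 ± 0.219, adjusted p = 0.00663) and Epx (−0.97 ± 0.185, adjusted p = 0.00384). Smaller falls were those of Mettl11b (−0.96 ± 0.169, adjusted p = 0.00263), Fam122b (−0.95 ± 0.182, adjusted p = 0.00386), Pi4k2b (−0.94 ± 0.16, adjusted p = 0.00221) and Epb4.1l4a (−0.93 ± 0.289, adjusted p = 0.0336). Slc1a2 rose by 1.27 ± 0.387 (adjusted p = 0.031), while Aqp4 (0.62, adjusted p = 0.109), Gja1 (0.54, adjusted p = 0.115), Aldh1l1 (0.03, adjusted p = 0.901) and Gfap (−0.10, adjusted p = 0.491) did not pass. Without stressed replicates 4 and 5 the rises of Ppp1r9a, Myo5a, Dync1h1, Sptan1, Sptbn1 and Mapk8ip2 were 1.34, 0.75, 1.10, 1.20, 1.15 and 0.45, the last no longer called (adjusted p = 0.0908). Without replicates 1 to 3 that of Slc1a2 was 0.00 (adjusted p = 0.997).

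Neuron, microglia, chaperone, calcium signalling and synapse-organizing genes rose as groups here too. General neuron genes rose for 11 of 16 (13 adjusted over the list alone; camera adjusted p = 2.26e-05, adjusted p = 0.41 with an estimated correlation). Chaperones rose for 16 of 25 (19 adjusted over the list alone; camera adjusted p = 7.17e-06, adjusted p = 0.336 with an estimated correlation). Calcium and cyclic AMP signalling genes rose for 13 of 26 (17 adjusted over the list alone; camera adjusted p = 8.8e-06, adjusted p = 0.336 with an estimated correlation). Synapse-organizing genes rose for 13 of 22 (16 adjusted over the list alone; camera adjusted p = 2.26e-05, adjusted p = 0.41 with an estimated correlation). Microglia genes rose for 10 of 15 (11 adjusted over the list alone; camera adjusted p = 0.000396, adjusted p = 0.441 with an estimated correlation). Meningeal fibroblast genes rose for 8 of 11 (10 adjusted over the list alone; camera adjusted p = 0.00315, adjusted p = 0.491 with an estimated correlation). Core astrocyte genes had 3 higher and 2 lower of 24 (3 and 2 adjusted over the list alone; camera adjusted p = 0.334). Oxidative phosphorylation had 2 higher of 34 (0 adjusted over the list alone; median −0.05; camera adjusted p = 0.606) and ribosomal proteins had 1 lower of 81 (0 adjusted over the list alone; median 0.07; camera adjusted p = 0.676). EdgeR called 2210 genes higher and 1665 lower, 3875 of 15491, and camera 14 of 35 lists. The count of genes was 2109 without resilient replicate 1, 1938 without replicate 2 and 2536 without replicate 3. It was 0 with the marker level as a covariate, 2996 with the replicate block, 5859 without stressed replicates 4 and 5, and 7178 without stressed replicates 1 to 3.

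Genes that changed in stressed mice against both other groups are those the study design sought. Lrp1 (mm10 chromosome 10, 127538161 to 127621148, minus strand) led them, at 114 ± 11.8 CPM in stressed, 36.2 ± 6.27 in resilient and 27.8 ± 3.92 in control mice, a change of 2.04 ± 0.158 against control and 1.66 ± 0.139 against resilient. Celsr2, an adhesion receptor of the cadherin family, rose by 2.01 and 1.76, Atp2b4, a calcium pump, by 1.72 in both comparisons and Ncam2, a cell adhesion gene, by 1.73 and 1.29. Ccdc47, a protein of the endoplasmic reticulum, rose by 1.67 and 1.48, Sel1l, which serves degradation of misfolded proteins there, by 1.59 and 1.30, Pcdh7, a protocadherin, by 1.43 and 1.11, and Cds2, an enzyme of phospholipid synthesis, by 1.31 and 1.09. Their positions on mm10 are chromosome 3, 108390851 to 108415552 (Celsr2), chromosome 1, 133699457 to 133801041 (Atp2b4), chromosome 16, 81200697 to 81626828 (Ncam2), chromosome 11, 106197408 to 106216344 (Ccdc47), chromosome 12, 91806043 to 91849157 (Sel1l), chromosome 5, 57717967 to 58133230 (Pcdh7) and chromosome 2, 132263148 to 132312050 (Cds2), all annotated as protein coding. The rise of Lrp1 against control was 2.06 without stressed replicates 4 and 5 and 2.00 without replicates 1 to 3.

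In all, 1870 genes rose and 1281 fell in both comparisons, 3151 together, and 0 were called with opposite signs. The comparisons share the stressed libraries. In 40 simulations of this without true change, 0 genes were called in both and r across genes was 0.407 (observed 0.9). Library structure was not tested as a cause. Over 20 divisions of the stressed libraries between comparisons, 716 to 2856 genes were shared (median 1203) and r was 0.341 to 0.767. It was lowest, and the shared genes most, with replicates 1 to 3 apart from 4 and 5. The 3151 became 1394 to 3338 leaving out 1 library, 0 with the marker covariate and 2079 with the block.

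Resilient and control mice were close in the prefrontal cortex, which asks whether resilience left a mark of its own. EdgeR called 0 of 15491 genes; 364 had an unadjusted p under 0.05. The genes with the smallest p were Zfp783 (0.47 ± 0.114), the clock gene Ciart (0.74 ± 0.181), the opsin gene Opn1sw (−0.90 ± 0.248) and Rps27 (−0.42 ± 0.12), each with adjusted p = 1. Within the long naming form (2 control and 3 resilient libraries) 15 genes were called. Camera called 8 lists, all with adjusted p = 0.53 with an estimated correlation. These were ribosomal proteins (median −0.25, camera adjusted p = 1.48e-24), oxidative phosphorylation (−0.17, adjusted p = 2.07e-07), red blood cells (1.24, adjusted p = 1.71e-05, with 4 of 4 genes higher adjusted over the list alone) and synapse-organizing genes (0.30, adjusted p = 2e-04). The others were cholesterol synthesis (0.14, adjusted p = 0.0011), striatal projection neurons (0.20, adjusted p = 0.00765), immediate early genes (−0.11, adjusted p = 0.0227) and neuromodulator receptors (0.20, adjusted p = 0.0272).

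Levels of cell-type markers per library addressed how much RNA of other cells came along. In the prefrontal cortex the mean log2 CPM of general neuron markers was 7.16 ± 0.402 (SD, n = 5) in stressed, 6.25 ± 0.033 (n = 4) in resilient and 6.19 ± 0.404 (n = 3) in control libraries. All 5 stressed libraries lay above all control libraries (exact permutation p = 0.0179, the smallest this design allows; adjusted p = 0.0732). Microglia markers were at 1.66 ± 0.563, 0.62 ± 0.061 and 0.46 ± 0.185 (stressed against control, 5 of 5 above, exact permutation p = 0.0357, adjusted p = 0.115). Endothelial markers were at 0.76 ± 0.941 and −0.53 ± 0.284 in stressed and control libraries (exact permutation p = 0.0536, adjusted p = 0.15). Inhibitory neuron markers stood at 4.05 ± 0.19 against 3.07 ± 0.205 (exact permutation p = 0.0179, adjusted p = 0.0732). Core astrocyte markers were at 9.88 ± 0.447 in stressed and 9.50 ± 0.083 in control libraries (exact permutation p = 0.232, adjusted p = 0.36). Over the 4 regions 0 marker comparisons passed the adjustment.

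**Figure D3:**
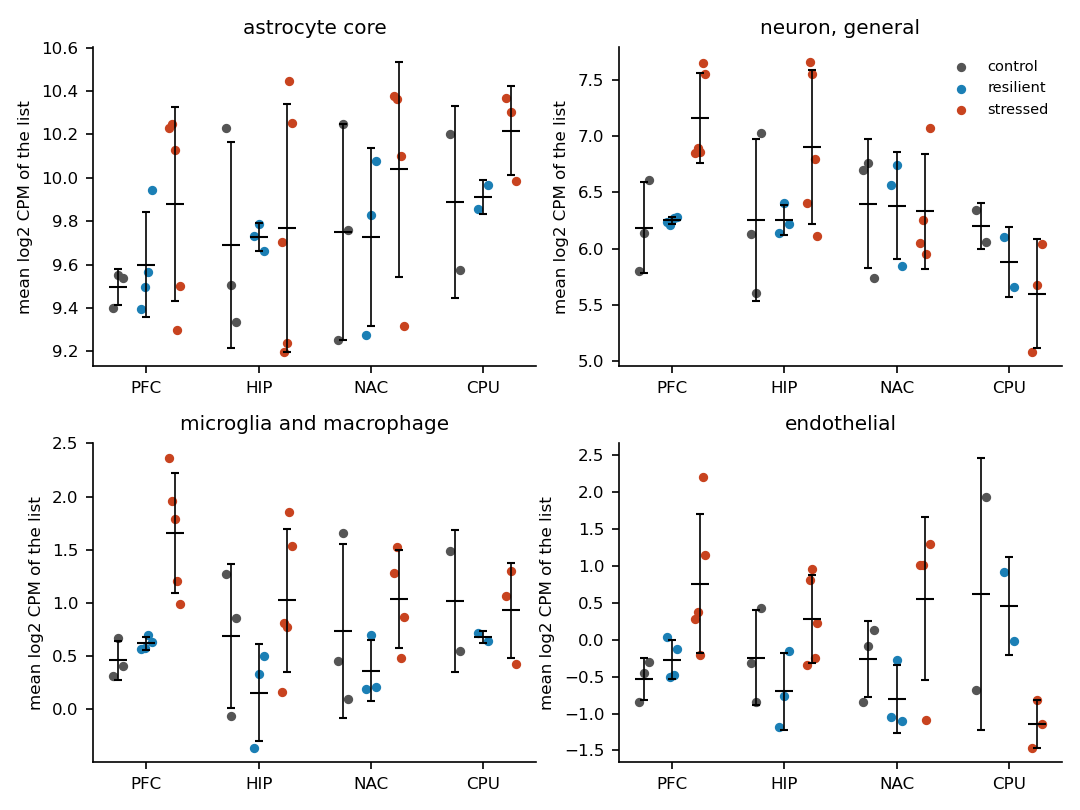
Marker level of each library (mean log2 CPM of the members of a list) for core astrocyte, general neuron, microglia and endothelial lists, by region (PFC prefrontal cortex, HIP hippocampus, NAC nucleus accumbens, CPU caudate putamen) and condition. Dots are libraries and bars show mean ± SD; in the prefrontal cortex the 5 stressed libraries lie above all control libraries for general neuron markers (7.16 against 6.19 on average).

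In the hippocampus no gene passed. Slc17a6, a vesicular glutamate transporter of neurons, stood at 6.90 ± 1.78 CPM in stressed (n = 5), 3.05 ± 0.205 in control (n = 3) and 2.15 ± 0.477 in resilient libraries (n = 3). The change was 1.18 ± 0.276 against control (adjusted p = 0.525) and 1.68 ± 0.284 against resilient (adjusted p = 0.268). Against control the others with the smallest p were Cdh22 (1.21 ± 0.283), Churc1 (−0.69 ± 0.169) and Phyhd1 (−0.73 ± 0.2), all with adjusted p = 0.525. Against resilient they were Zfhx3 (1.62 ± 0.34), Oasl1 (−1.82 ± 0.455) and Tmem52 (−0.83 ± 0.208), all with adjusted p = 0.268. Resilient against control, they were Fam227b (2.46 ± 0.561), Eif3j2 (1.84 ± 0.424), Cdc42ep3 (−1.04 ± 0.263) and Fndc9 (−3.52 ± 0.917), each with adjusted p = 1.

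Among hippocampal lists in stressed against control mice, general neuron genes (median 0.70, camera adjusted p = 0.000433, adjusted p = 0.656 with an estimated correlation), synapse-organizing genes (0.71, adjusted p = 0.000198) and calcium and cyclic AMP signalling (0.50, adjusted p = 0.000424) were higher by camera. Ribosomal proteins (−0.35, adjusted p = 3.09e-19) and oxidative phosphorylation (−0.35, adjusted p = 2.59e-07) were lower. The last 4 lists each had adjusted p = 0.554 with an estimated correlation, and 0 members of the 5 lists were called, also adjusted over the list alone. Stressed replicates 2 and 3 stood apart on component 1 (68.0 and 74.9, against −23.6 to −5.27 in the other stressed libraries), and only these 2 of 5 lay above all controls in general neuron markers (exact permutation p = 0.268). Without them the general neuron list was not called (median 0.05, camera adjusted p = 0.199). The other 4 lists stayed called, with medians of 0.60, 0.30, −0.15 and −0.14 and at least adjusted p = 0.673 with an estimated correlation. Against resilient mice microglia (1.14, adjusted p = 0.000752), endothelial (1.12, adjusted p = 0.00114), meningeal fibroblast (1.37, adjusted p = 0.000858) and chaperone genes (0.69, adjusted p = 0.000629) were higher by camera, each with adjusted p = 0.663 with an estimated correlation. Adjusted over the list alone, 7 chaperones, 8 calcium and cyclic AMP genes and 1 meningeal gene were higher. In resilient against control mice meningeal (−0.98, adjusted p = 3.45e-05) and microglia genes (−0.73, adjusted p = 0.000968) were lower by camera, with adjusted p = 0.971 with an estimated correlation. EdgeR called 0 of 15758 genes in all 3 comparisons, with 1312 genes at an unadjusted p under 0.05 in stressed against control (520 without stressed replicates 2 and 3), 2718 in stressed against resilient (1288) and 225 in resilient against control. DESeq2 called 0, 190 and 0. In stressed against resilient mice 556 genes were called without stressed replicate 1.

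In the nucleus accumbens the clock gene Ciart had the smallest p in stressed against control mice, at 36.3 ± 5.67 CPM in stressed (n = 4), 27.0 ± 3.99 in resilient (n = 3) and 16.6 ± 2.66 in control libraries (n = 3). It did not pass in edgeR (1.13 ± 0.18, adjusted p = 1) and was the 1 gene called by DESeq2 in stressed against control (adjusted p = 5.67e-05). The others with the smallest p there were Coq10b (0.50 ± 0.116), Sphk2 (−0.48 ± 0.141) and Hist2h2ac (−0.82 ± 0.254). Against resilient mice they were Anxa8 (2.63 ± 0.491), Nfkbia, an inhibitor of NF-kB (0.55 ± 0.142), Ptprh (−1.46 ± 0.389) and Prdm9 (−1.44 ± 0.419), each with adjusted p = 0.987. In resilient against control mice they were Ciart (0.70 ± 0.188), Coq10b (0.37 ± 0.123), Taf4a (−1.07 ± 0.245) and Gadd45g (−0.45 ± 0.113), each with adjusted p = 1.

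Endothelial genes were higher by camera in the stressed accumbens. In mean marker level 3 of 4 stressed libraries lay above all controls and 1 below (exact permutation p = 0.343). The list had a median of 1.32 against control (camera adjusted p = 1.3e-05, adjusted p = 0.688 with an estimated correlation). It was 1.94 against resilient (adjusted p = 1.81e-09, adjusted p = 0.413 with an estimated correlation), where 6 of 11 were higher adjusted over the list alone and 0 over all genes. Against resilient mice meningeal (1.42, adjusted p = 2.79e-06) and microglia genes (0.93, adjusted p = 1.31e-05) were higher, each with adjusted p = 0.52 with an estimated correlation. NF-kB genes were higher too (0.29, adjusted p = 8.83e-06, adjusted p = 0.377 with an estimated correlation), with 1 gene higher adjusted over the list alone. In resilient against control mice red blood cell genes (1.02, adjusted p = 3.11e-06) were higher and immediate early genes (−0.20, adjusted p = 2.39e-05) lower, each with adjusted p = 0.303 with an estimated correlation. Meningeal genes were lower as well (−1.07, adjusted p = 7.37e-05, adjusted p = 0.61 with an estimated correlation). EdgeR called 0 of 15283 genes in each comparison. At an unadjusted p under 0.05 were 179 for stressed against control, 302 against resilient and 119 for resilient against control (764.2 expected by chance). Without stressed replicate 4 they were 1149, 1859 and 303, and without control replicate 2 they were 1259, 499 and 152.

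In the caudate putamen lower genes with the smallest p in stressed against control mice were Pcp4, a calmodulin regulator of striatal neurons (5.45 ± 1.38 CPM, n = 3, against 17.2 ± 1.9, n = 2; −1.66 ± 0.255), and Rprml (−1.04 ± 0.153). The vesicle traffic genes Ap3s1 (0.65 ± 0.12) and Rab10 (0.56 ± 0.105) were higher. None passed in edgeR (adjusted p = 0.457 for each); DESeq2 called all 4, with adjusted p = 8.79e-05 for Pcp4 and 0.000168 for Rprml. Against resilient mice Irf2bp2, a transcriptional corepressor, stood at 97.4 ± 1.46 against 34.8 ± 5.64 CPM (1.49 ± 0.196) and Ski, which represses TGF-beta signalling, at 1.53 ± 0.245. Clic5 (0.0136 CPM in stressed libraries, near 0 counts, so no fold is given) and Calcrl (−2.17 ± 0.563) were lower, each with adjusted p = 0.939 in edgeR. In resilient against control mice Rab10 (0.66 ± 0.114), Vps29 (0.68 ± 0.119), Irf2bp2 (−1.32 ± 0.208) and Gap43 (−1.04 ± 0.191) had the smallest p (adjusted p = 0.558).

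Endothelial genes of the caudate putamen were lower by camera in stressed mice, with a median of −2.95 against control (camera adjusted p = 2.15e-05, adjusted p = 0.601 with an estimated correlation; 8 of 11 lower adjusted over the list alone, 0 over all genes). The 2 control libraries lay at −0.68 and 1.93 mean log2 CPM of this list, and the difference of stressed from control means was −1.77, or −0.47 without control replicate 2. The median was −2.05 against resilient (adjusted p = 4.47e-06, adjusted p = 0.765 with an estimated correlation). Excitatory neuron genes (−1.06, adjusted p = 4.17e-05; 3 lower adjusted over the list alone) and general neuron genes (−0.49, adjusted p = 4.18e-05; 5 lower adjusted over the list alone) were lower against control and core astrocyte genes higher (0.26, adjusted p = 0.00113), each with adjusted p = 0.601 with an estimated correlation. Ependymal genes were higher against resilient mice (0.69, adjusted p = 3.1e-06, adjusted p = 0.765 with an estimated correlation) and lower in resilient against control mice (−0.73, adjusted p = 0.000207, adjusted p = 0.607 with an estimated correlation; 1 lower adjusted over the list alone). EdgeR called 0 of 14958 genes in each comparison, with 1430, 382 and 1234 genes at an unadjusted p under 0.05 (747.9 expected by chance), in the order given for the accumbens. DESeq2 called 40, 3 and 29, limma voom 0.

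Whether the effect of stress differed between regions was tested directly. Genes nearest to such a difference were Taf9, a subunit of the basal transcription machinery, with stressed against control changes of −0.26 in the prefrontal cortex, −0.23 in the hippocampus, 0.09 in the accumbens and 0.48 in the caudate putamen (adjusted p = 0.173). Ube2d3, a ubiquitin-conjugating enzyme, was next (−0.53, −0.21, 0.01 and 0.44, adjusted p = 0.173). Against resilient mice they were Anxa8 (−0.11, 0.32, 2.64 and 1.86, adjusted p = 0.699) and Col6a1 (2.74, 2.51, 0.01 and −0.70, adjusted p = 0.699). EdgeR called 0 of 16759 genes for either contrast (2108 and 1168 at an unadjusted p under 0.05), so the prefrontal changes are not shown to differ from those of other regions. DESeq2 called 240 and 0 genes, and limma voom 838 and 1081 for the contrasts. Leaving out hippocampal stressed replicate 1 gave 55 genes for stressed against control, hippocampal control replicate 1 gave 2 and caudate putamen control replicate 1 gave 1. No gene was called in 3 or more regions.

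The genes called in both prefrontal comparisons were scored in the other regions. The score of a library is the mean log2 CPM of the 1870 higher genes minus that of the 1281 lower genes. In the hippocampus stressed libraries scored −1.09 ± 0.76 (SD, n = 5) and the other libraries −2.09 ± 0.455 (n = 6), with 3 of 5 stressed libraries above all others (exact permutation p = 0.0303, adjusted p = 0.0909 over 3 regions; exact permutation p = 0.19 without stressed replicates 2 and 3). In the nucleus accumbens the means were −1.63 ± 0.379 (n = 4) and −1.95 ± 0.435 (n = 6; exact permutation p = 0.238, adjusted p = 0.357), a difference of 0.32, or 0.18 without stressed replicate 4. In the caudate putamen they were −1.87 ± 0.198 (n = 3) and −1.83 ± 0.34 (n = 4; exact permutation p = 0.8, adjusted p = 0.8). Averaged over the 3 regions stressed libraries scored 0.43 higher than the rest (permutation test within regions, p = 0.0244). Without the 4 stressed libraries that had a length trend (hippocampus 2 and 3, accumbens 4, caudate putamen 3) it was 0.20 (exact permutation p = 0.254).

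**Figure D4:**
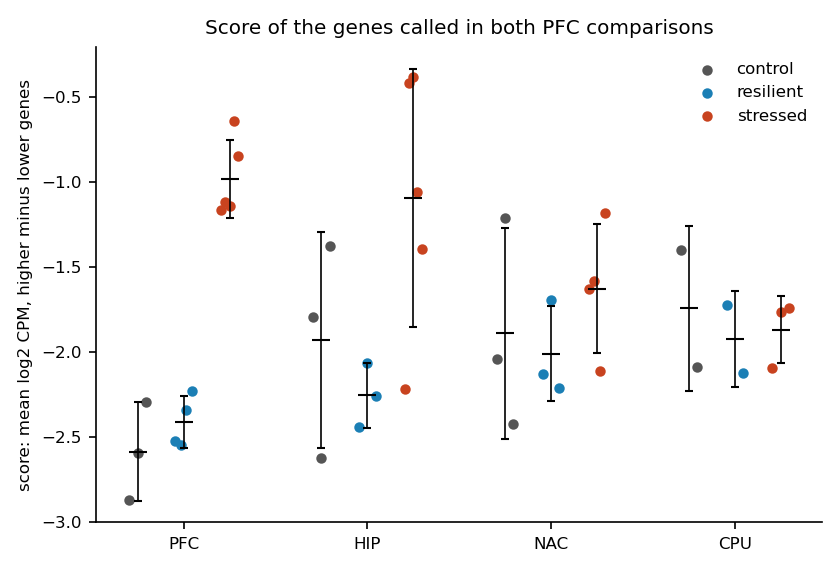
Score of the genes called in both prefrontal comparisons (mean log2 CPM of the higher minus the lower genes) in each library, by region (abbreviated as above) and condition. Dots are libraries and bars show mean ± SD; the prefrontal libraries, from which the genes were chosen, are shown for scale, and hippocampal stressed libraries averaged −1.09 against −2.09 for the other hippocampal libraries.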

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

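Except for the planned marker covariate, the tests of patterns in the prefrontal cortex, the counts of other splits and the values without chosen libraries were chosen only after the result was seen, while the tests of prefrontal genes in the other 3 regions were set before their outcome was known.

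The prefrontal stressed libraries stood apart from control and resilient ones, with 4353 genes called against control. The tables argue against a transcript length or GC trend as the whole cause, since 3494 of these genes stayed called with their sign after each library's trend was removed, and against the naming form of the deposited files, since 3738 stayed called with their sign within the long form and 2167 within the short form (with 1 control, assumed to vary like the other groups). A lower share of astrocyte RNA is argued against for stressed replicates 1 to 3, where 14 core astrocyte genes were called higher and 2 lower and the list lay at 10.20 ± 0.066 mean log2 CPM against 9.50 ± 0.083 in controls (SD, n = 3 each), but cannot be told apart for replicates 4 and 5, where 1 was called higher and 7 lower. RNA of other cell types carried along could not be told apart from the stress group: with the marker level as a covariate edgeR called 0 genes (4462 at an unadjusted p under 0.05), the median change in the called direction went from 0.70 to 0.24 and the median standard error from 0.17 to 0.35; group explained 87.4% of the covariate, which widens the errors, with the lowest stressed library (3.49) above the highest of the others (2.97), and why the changes shrank was not tested. An effect of defeat on astrocytes, on the other cells, or on what the purification carries along may each remain, and these data do not separate them.

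The prefrontal stressed libraries fell into 2 kinds. Across genes, replicates 4 and 5 showed a correlation of expression change with log2 transcript length of 0.424 and 0.372, against −0.127 to 0.01 in replicates 1 to 3 and −0.279 to −0.101 in control and resilient libraries, and replicates 1 to 3 had more of the ribosomal RNA precursor gene Rn45s (11.12 to 11.26 log2 CPM). Replicates 4 and 5 had the long naming form and replicates 1 to 3 the short one. The naming form alone is argued against, because long-form control and resilient prefrontal libraries reached at most −0.101. No biological explanation was tested, and an unlabelled batch within the stressed group may remain.

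Genes called in both prefrontal comparisons scored higher in stressed libraries of the other 3 regions, by 0.428 on average (permutation test within regions, p = 0.0244), which is consistent with a pattern tied to the stress group beyond the prefrontal cortex. The excess was 1.00 in the hippocampus, 0.32 in the accumbens and −0.04 in the caudate putamen, and 0.54, 0.18 and −0.10 (0.20 on average, exact permutation p = 0.254, so the support is lost) without stressed libraries with a length trend, among them the highest scores of the first 2 regions (hippocampal replicates 2 and 3, accumbens replicate 4). These 3 were not Rn45s-rich (9.94 to 10.55 log2 CPM), and for the others an Rn45s-rich kind of library stays open: of the 3 control libraries with high Rn45s outside the prefrontal cortex, 2 scored above every other control and resilient library of their region, while hippocampal control replicate 1 lay below control replicate 3. The score may also follow carried-along RNA, which was not separated from stress here.

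Other splits of the same libraries were counted for each comparison with at least 3 libraries per group. Unadjusted shares argue against chance for 4353 genes of prefrontal stressed against control (1 of 56 splits gave as many, the minimum). Next came 3332 (stressed replicates 3 to 5 against the rest). The same holds for 3875 against resilient (1 of 100 drawn, highest other 2068) and 3151 in both (1 of 100, highest other 0). Chance stays open for 19 lists against control (2 of 56, highest other 20), all lost with an estimated correlation (adjusted p from 0.132). It cannot be excluded for the 14 lists of prefrontal stressed against resilient (22 of 100, highest other 19) or for the 8 lists of resilient against control (16 of 35, highest other 15), nor in the hippocampus for the 11 lists of stressed against control (33 of 56, highest other 17) or the 14 of stressed against resilient (20 of 56, highest other 18). Where 0 genes were called, every split gives as many and the count says nothing about chance: prefrontal resilient against control (35 of 35, highest other 0), hippocampal stressed against control (56 of 56, highest other 5088), stressed against resilient (56 of 56, highest other 2818) and called in both (100 of 100, highest other 1). The split with 5088 genes set stressed replicates 2 and 3 and control replicate 3, all of the long naming form, against the rest, which points to a structure of the libraries other than the groups; the split with 2818 genes likewise set stressed replicates 2 to 4 against the rest. Within the long form (1 resilient library) and the short form (1 control) edgeR called 0 genes in hippocampal stressed against control (935 and 363 at an unadjusted p under 0.05), and 0 and 226 against resilient.

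In the nucleus accumbens chance cannot be excluded for the 16 lists of stressed against control (13 of 35 splits, highest other 22) or the 15 of stressed against resilient (12 of 35, highest other 22). With 0 genes called the splits again say nothing about chance, for stressed against control (35 of 35, highest other 1478), stressed against resilient (35 of 35, highest other 0) and called in both (100 of 100, highest other 664). The splits with 1478 and 664 genes, which set stressed replicate 4 and control replicates 1 and 3 (with resilient replicate 1 in the latter) against other libraries, point to such a structure too. Resilient against control has only 10 splits in the hippocampus and in the accumbens, too few for a share under 0.05: the hippocampus had 0 genes (10 of 10 splits, as any would with 0, highest other 0) and 8 lists (8 of 10, highest other 14), and the accumbens 0 genes (10 of 10, highest other 0) and 11 lists (7 of 10, highest other 18).

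Single libraries far from the rest of their group are given with their gap to the nearest library as a share of the group's range; 9 of 150 values tested were that far, where 7.5 would be by chance, at about 1 in 20 groups. In accumbens stressed replicate 4 the correlation with log2 transcript length across genes was 0.363, against −0.199 to −0.164 in the other libraries (0.938). Hippocampal stressed replicate 3 had a total count of 30.3 M, against 25.2 to 26.3 M (0.793). Endothelial markers were at −1.09 mean log2 CPM in accumbens stressed replicate 3, against 1.01 to 1.29 (0.882). Meningeal fibroblast markers were at 5.13 in hippocampal stressed replicate 5, against 2.95 to 3.39 (0.796). Red blood cell markers were at 1.69 in prefrontal resilient replicate 4, against 2.76 to 2.92 (0.871). Myo5a was at 5.41 log2 CPM in prefrontal resilient replicate 1, against 5.16 to 5.19 (0.872), and Atp2b4 at 2.46 in resilient replicate 2, against 2.56 to 2.58 (0.854). Fbxl21 was at 2.01 in prefrontal stressed replicate 2, against 1.55 to 1.64 (0.805), and Cds2 at 6.20 in stressed replicate 5, against 6.58 to 6.64 (0.856).

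Marker levels of 4 lists moved in opposite directions in the prefrontal cortex and the caudate putamen in stressed against control mice, with every stressed library above every control library in the first region and below in the second; the difference between regions was not tested. General neuron markers differed by 0.97 in the prefrontal cortex and by −0.60 in the caudate putamen (a gap of 1.575). Excitatory neuron markers differed by 1.03 and −1.22 (2.242), oligodendrocyte precursor markers by 0.60 and −0.24 (0.831; the medians of this list differed by 0.54 and 0.10, so without a turn), and endothelial markers by 1.29 and −1.77 (3.062; −0.47 in the caudate putamen without control replicate 2). Among reads outside genes, which no comparison used, ambiguous reads made up 4.17% ± 0.026 (SD, n = 2) in resilient and 4.101% ± 0.014 (n = 3) in stressed libraries of the caudate putamen, against 3.99% ± 0.034 (n = 2) in controls (exact permutation p = 0.333 and p = 0.1, the smallest these designs allow; 24 such shares were compared).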

How the results depend on the processing

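Comparisons within 1 naming form, without chosen stressed replicates, and with the length and GC trend removed were chosen only after the data were seen; the other tests here were planned. Of 132 called results of named genes, 19 kept their direction and call under every alternative, 108 lost the call under at least 1 and 25 changed sign under at least 1; of 57 results that were not called, 27 stayed so with their sign, 29 were called under at least 1 and 6 changed sign. Unless stated, the cause of a change was not tested. Depth was 21.3 to 33.0 M counts per library; in simulated data edgeR found 64.2% of 2-fold changes in prefrontal and 23.9% in hippocampal stressed against control, so smaller changes would often be missed.

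Called genes, prefrontal stressed against control: 2878 with all 40 libraries in 1 fit, 2875 with the replicate block, 0 with the marker covariate (4462 at an unadjusted p under 0.05), which group mostly explains, 8394 within the long form, 7600 without stressed replicates 1 to 3, and 1533 to 4645 leaving out 1 library (1533 without control 1, 2178 without control 2). Stressed against resilient: 6771 with limma voom, 2548 in 1 fit, 0 with the covariate (4642 at an unadjusted p under 0.05), 7990 within the long form, 5859 without stressed replicates 4 and 5, 7178 without replicates 1 to 3, and 1938 to 4013 leaving out 1 library (2109, 1938 and 2536 without resilient 1, 2 and 3). Resilient against control: 15 within the long form, and 8 within the short form, where each group is 1 library that is assumed to vary like the other groups. Called in both: 5054 with limma voom, 1851 in 1 fit, 2079 with the block, 0 with the covariate, 7164 within the long form, 6466 without replicates 1 to 3, and 1394 to 3338 leaving out 1 library (1394 and 1800 without control 1 and 2, 1873 and 1774 without resilient 1 and 2). Hippocampal stressed against resilient: 190 with DESeq2, 1266 in 1 fit, 226 within the short form, and 0 to 556 leaving out 1 library (556 without stressed 1). DESeq2 called 1 gene in accumbens stressed against control and 40, 3 and 29 in the caudate putamen, where 1 was called against resilient without a filter. Interaction: 240 with DESeq2, 838 and 1081 with limma voom, and 0 to 55 leaving out 1 library (2 without hippocampal control 1, 55 without hippocampal stressed 1, 1 without caudate putamen control 1). Region differences: 4913 with DESeq2, 1811 with the block, 4596 in 1 fit, and 1784 to 3539 leaving out 1 library (1806, 1784 and 1973 without prefrontal control 1, 2 and 3). Gene lists: 0 in all 12 comparisons with an estimated correlation and 0 in 10 with fry; with the covariate 9 (hippocampus) and 23 (accumbens) against resilient, and 2 and 5 in the caudate putamen against control and resilient. Leave-one-out counts were 0 in the remaining comparisons. Same-numbered libraries correlated best with their own number in 15 of 34 cases.

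With the marker covariate, signs turned against control for Ppp1r9a (−2.25), Myo5a (−2.69), Dync1h1 (−2.09), Myh10 (−2.27), Bsn (−0.80), Mapk8ip2 (−2.92), Ryr2 (−1.07), Aldh1l1 (−0.46), Gfap (0.15), Slc17a7 (−0.45), Reln (−0.22), Enpp2 (−0.40), Dnah5 (−0.88), Ptgs2 (−1.13), Ppp1r3c (0.014), Ndufb10 (0.30), Cnr1 (−0.33), Rps27 (0.13) and Rpl7l1 (0.062), and against resilient for Ppp1r9a (−1.34), Myo5a (−1.94), Dync1h1 (−1.29), Sptan1 (−1.17), Mapk8ip2 (−2.03), Sptbn1 (−0.86), Bsn (−0.43), Aldh1l1 (−0.40) and Gfap (0.16). Aldh1l1, near 0, also turned against control with the block (−0.10), the form term (−0.005), the trend removed (−0.087), within the short form (−0.30), without replicates 4 and 5 (−0.066) and leaving out 1 library (−0.048 to 0.16), and against resilient with the form term (−0.016), the trend removed (−0.034), within the short form (−0.48), without replicates 4 and 5 (−0.066) and leaving out 1 library (−0.051 to 0.21). Within the long form Hbb-bs (−0.35) and B2m (−0.11) turned against control and Aqp4 (−0.14) against resilient; without replicates 1 to 3 B2m (−0.03) and Aqp4 (−0.23) did.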

Other observations

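The gene lists and their tests were set before the data were examined, and looking at 1 list side by side over the regions was chosen only after the result was seen.

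In control mice the purified RNA carried regional marks of neighbouring cells, each region compared with the mean of the other 3. Ependymal genes were higher in the hippocampus (8 of 9 called, median 2.69, camera adjusted p = 3.17e-06, adjusted p = 0.39 with an estimated correlation). Excitatory neuron genes were higher in the hippocampus (7 of 12, median 1.48, adjusted p = 3.53e-05, adjusted p = 0.39 with an estimated correlation) and in the prefrontal cortex (6 of 12, median 1.29, adjusted p = 0.0067, adjusted p = 0.755 with an estimated correlation). Oligodendrocyte genes were lower in the prefrontal cortex (9 of 14, and 13 adjusted over the list alone; median −1.43, adjusted p = 7.24e-07, adjusted p = 0.511 with an estimated correlation). Meningeal genes were lower in the caudate putamen (7 of 11, and 8 adjusted over the list alone; median −3.06, adjusted p = 7.81e-08, adjusted p = 0.586 with an estimated correlation), where 2 control libraries were compared.

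Ribosomal protein genes were lower in resilient than in control mice in each of the 4 regions by camera. Outside the prefrontal cortex the median was −0.16 in the hippocampus (4 of 81 genes above 0; adjusted p = 2.96e-06, adjusted p = 0.971 with an estimated correlation), −0.15 in the nucleus accumbens (5 of 81; adjusted p = 8.6e-15, adjusted p = 0.618 with an estimated correlation) and −0.26 in the caudate putamen (8 of 81; adjusted p = 8.61e-11, adjusted p = 0.823 with an estimated correlation). These genes move together, with estimated correlations of 0.66 to 0.888, and edgeR called 0 of them in any region.

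Over all regions 6 of 17 stressed libraries and 0 of 23 others correlated over 0.3 with log2 transcript length across genes (not independent replicates). Prefrontal stressed replicates 4 and 5, hippocampal 2 and 3 (0.389 and 0.45) and accumbens 4 (0.363) had the long naming form. Caudate putamen 3 (0.368) had the short one. Other long-form libraries reached at most 0.031. Whether this trend comes from RNA handling, a batch or the animals was not tested.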
